A study of Mus musculus with 8 samples.

How the data were processed

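Alveolar macrophages of WT mice and of mice without 5-HT2C, stimulated with 10 µM serotonin for 4 h or left unstimulated, were measured on 8 Agilent 2-colour arrays, 4 per genotype. Per the labels, each array held stimulated RNA in one dye and unstimulated RNA of the same genotype in the other, with the dyes exchanged on 2 of the 4 arrays of a genotype. Genotype and replicate number were taken from the sample titles and the dye from the channel labels. The labels call the arrays biological replicates.

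The values used were the log ratios in the deposited value table, taken as log2 because limma, named without a version in the submitters' processing notes, gives log2 ratios. The deposited log2 values have array medians near 0, as normalised ratios have. The background correction, the normalisation method, the log base and the direction of the ratio are not given in the sources used here. If the base is another, every size given would change by one factor, and no test or count would change except the counts over 0.5 and 1. Channel intensities were not used here, so signal over background is unknown for every row. The deposited values have 15 significant digits (median) on arrays with the stimulated RNA in Cy5 and 6 on those with it in Cy3.

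The probe table lists 33074 of 44290 row numbers with 1 gene symbol and 56 with several, and 11160 have none. It was set against the values before any gene was named. For the 8164 symbols with 2 or more rows, the first and last row of a symbol correlated between -0.0092 and 0.019 across symbols within an array. How many rows share one identical value on an array was also ranked per row, since rounded or dim spots share values. Rows of one symbol had a Spearman rho of -0.0078 for that rank, inside the range from -0.036 to 0.037 of 1000 permutations of the symbols. Because the numbers did not match, no gene name was used. Each row was tested as a feature of its own, in place of the planned mean per gene symbol, and the planned gene lists and cell type markers were not run. The rule fixed before the data were examined named the 10 most positive and 10 most negative called genes of each comparison and a set of cytokine, immediate early and serotonin receptor genes. Without gene names, at most 2 rows per sign, the largest past the threshold, are given for each comparison, in both readings of the direction.

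The design fixed before the data were examined takes the values as Cy5 over Cy3 and changes the sign on arrays with the stimulated RNA in Cy3, with the values as deposited as the alternative. Control probes that could settle the direction could not be told from other rows. The fit as deposited is therefore given beside the other throughout.

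Rows with at least 3 values per genotype were tested (40891 rows). One linear model over all 8 arrays had a term for the log2 ratio in WT, one for KO and one dye term common to both, and was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The ratios in WT and KO, their difference and their mean were tested against 0. P-values were adjusted by the Benjamini-Hochberg method over all rows, with a threshold of 0.05. Checks of row order and of shared values used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. The model was tested on simulated data with the spread of the WT comparison over 40891 rows: 42% of 100 changes of 0.25 and 92% of 100 changes of 0.5 on the log2 scale were recovered, and 8 unchanged rows were called.

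Alternatives were the opposite reading of the direction, no dye term, another centring or scaling of arrays, rows with values on all 8 arrays, leaving out the rows of low variance, robust eBayes, array weights, separate fits per genotype, replicate number as a block, and leaving out each array. A dye term per genotype, that term with the values as deposited, and a filter on shared values were added after seeing the data.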

Results

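Alveolar macrophages, the resident phagocytes of the air spaces of the lung, were taken from wild-type mice (WT) and from mice lacking the serotonin receptor 5-HT2C (KO), a G protein-coupled receptor. In culture the cells were either given 10 µM serotonin for 4 h or left unstimulated. RNA of stimulated and unstimulated cells of one genotype was hybridised together, in different dyes, on a 2-colour array. There were 4 arrays per genotype, named by the labels as biological replicates. In each genotype, 2 arrays had the stimulated RNA in Cy5 and 2 had it in Cy3, so that dye and stimulation were balanced. The KO arrays with stimulated RNA in Cy5 were replicates 3 and 4, and the WT arrays were replicates 1 and 2.

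Each array gave one log ratio for each of 44290 numbered rows. Between 473 and 10843 rows had no value on a given array, and 25382 rows had a value on all 8. The medians of the WT arrays were 0.00019, -0.000026, -0.0037 and -0.0019 for replicates 1 to 4, and those of the KO arrays were -0.0035, -0.0035, 0.0013 and 0.0064. The SD over rows was between 0.136 and 0.192. The number of arrays limits the precision: the median standard error of a fitted log2 ratio was 0.0440 in WT and 0.0450 in KO. The gene of a row is not named here, because the row numbers did not match the probe table at hand (rows of one gene symbol correlated between -0.0092 and 0.019 within an array). Gene groups and cell type markers were therefore not described, and the deleted receptor gene itself could not be checked.

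The labels give the dye of each RNA, but not whether a deposited ratio is Cy5 over Cy3 or already stimulated over unstimulated. Each comparison is given under both readings. In the first, values were taken as Cy5 over Cy3 and the sign was changed on arrays with the stimulated RNA in Cy3 (turned ratios). In the second, values were used as deposited. A positive sign means more RNA in stimulated cells only under the reading it is given for, so signs are not described as rises or falls.

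The arrays of one genotype fell apart by dye. As deposited, WT arrays with the stimulated RNA in the same dye correlated with each other across rows (mean Pearson r 0.587 over 2 pairs), whereas WT arrays of opposite dyes were anticorrelated (mean r -0.328 over 4 pairs, from -0.383 to -0.244). In KO the same-dye mean was 0.562 and the opposite-dye mean was -0.506, from -0.600 to -0.433. Between a WT and a KO array the mean r was -0.045 for the same dye and 0.044 for opposite dyes, over 8 pairs each. These are correlations across rows, which are not independent replicates.

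**Figure D1:**
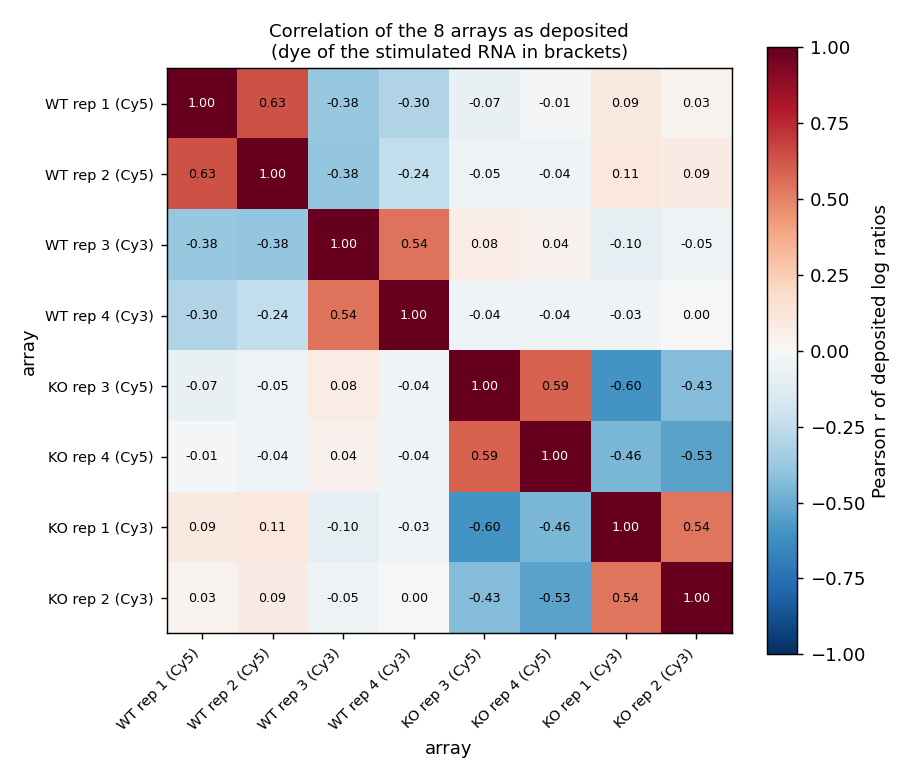
Pearson r of the deposited log ratios across rows for every pair of the 8 arrays, with the dye of the stimulated RNA in brackets and colour from -1 (blue) to 1 (red). Within a genotype, pairs of the same dye lie at 0.537 or above and pairs of opposite dyes at -0.244 or below, while pairs of a WT and a KO array lie between -0.096 and 0.106.

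The first question was which transcripts respond to serotonin in WT macrophages. With turned ratios, 4006 of 40891 rows tested differed from 0 (limma, Benjamini-Hochberg threshold 0.05), 1680 with a positive and 2326 with a negative sign. Most of these ratios were small: their median size was 0.23 on the log2 scale, 186 exceeded 0.5 and 1 exceeded 1. Row 28310 had the most negative called ratio, with a mean of -1.06 ± 0.18 (SD, n = 4; limma adjusted p = 0.000162), followed by row 25774 at -0.95 ± 0.17 (SD, n = 4; limma adjusted p = 0.000151). The most positive were row 38804 at 0.91 ± 0.30 (SD, n = 4; limma adjusted p = 0.00555, but 0.0514 with robust eBayes, which ends the call) and row 18226 at 0.90 ± 0.26 (SD, n = 4; limma adjusted p = 0.000154). Each of these rows had one sign on 4 of 4 turned WT arrays.

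As deposited, 91 WT rows differed from 0 by the same limma test, 61 positive and 30 negative. In these fits none of them was among the 4006 rows above. Little overlap was possible, since a WT ratio of one sign as deposited enters the residual of the turned fit in part. The rows called as deposited were fewer but larger, with a median size of 0.50, 45 over 0.5 and 7 over 1 on the log2 scale. Row 42029 had a mean of 1.80 ± 0.56 (SD, n = 4; limma adjusted p = 0.000193) and row 18866 a mean of 1.76 ± 0.20 (SD, n = 4; limma adjusted p = 1.92e-05). The most negative were row 27203 at -0.87 ± 0.19 (SD, n = 4; limma adjusted p = 0.00183) and row 29656 at -0.75 ± 0.07 (SD, n = 4; limma adjusted p = 0.0156). All 4 had one sign on 4 of 4 WT arrays, whichever dye held the stimulated RNA. With a dye term of its own for each genotype, an alternative chosen after seeing the data, 528 WT rows passed as deposited. Of these, 55 were among the 4006, which make up 9.8% of all rows tested. The median size of the 528 was 0.29, against 0.22 for the 4736 WT rows called by that model with turned ratios. As deposited, a common dye term leaves in the residual what changes sign with the dye differently in WT and KO, so smaller ratios pass less easily. The median standard error in WT as deposited was 0.0485 with the common term and 0.0431 with a term per genotype.

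The counts in WT were lower whichever WT array was left out. With turned ratios, 1826 rows passed without WT replicate 1, 2121 without WT replicate 2, 1913 without WT replicate 3 and 2663 without WT replicate 4. As deposited, 36 rows passed without WT replicate 1, 35 without WT replicate 2, 32 without WT replicate 3, 28 without WT replicate 4 and 57 without KO replicate 4. Leaving out an array also left fewer rows tested, fewer arrays and an unbalanced dye assignment. The lower counts therefore do not show that a single array carries the result.

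The same question was asked of KO macrophages. With turned ratios, 4337 rows differed from 0 (limma, Benjamini-Hochberg), 2124 positive and 2213 negative, with a median size of 0.25 on the log2 scale. Of these, 313 exceeded 0.5 and 30 exceeded 1. Row 35229 had a mean of -1.72 ± 0.18 (SD, n = 4; limma adjusted p = 3.22e-05), and row 27184 a mean of -1.66 ± 0.26 (SD, n = 4; limma adjusted p = 7.0e-05). The most positive were row 523 at 0.96 ± 0.09 (SD, n = 4; limma adjusted p = 6.36e-05) and row 37531 at 0.81 ± 0.14 (SD, n = 4; limma adjusted p = 4.09e-05). Without KO replicate 1 the count was 2578, and without KO replicate 3 it was 2166.

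As deposited, 0 KO rows passed the limma test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.999), and 1552 rows had an unadjusted p under 0.05. That is fewer than a share of 0.05 of the 40891 rows tested, which chance alone would give. With a dye term of its own for each genotype the count was also 0, with 3083 rows at an unadjusted p under 0.05 and a smallest limma adjusted p = 0.186. The 3083 rows are more than that share.

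**Figure D2:**
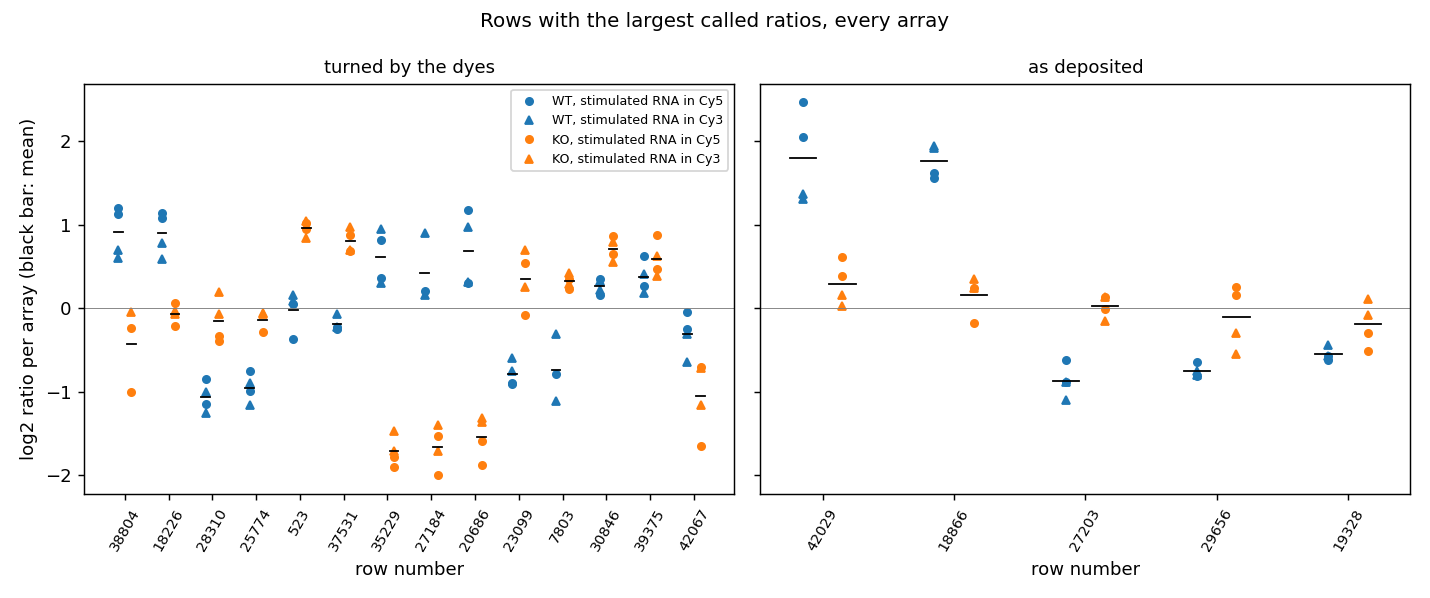
Log2 ratio of every array (points; circles for stimulated RNA in Cy5, triangles for Cy3; blue for WT, orange for KO) and the mean of each genotype (black bars) for the rows named here, turned by the dyes (left) and as deposited (right). Turned, the 4 KO values of row 35229 lie between -1.90 and -1.48 and its 4 WT values between 0.31 and 0.95, whereas as deposited the 4 WT values of row 18866 lie between 1.56 and 1.95 and its KO values between -0.18 and 0.35.

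The genotypes were then compared with each other, to see whether the ratios differ between WT and KO. No array held both genotypes, and the KO arrays also differed from the WT arrays in technical measures given at the end. A difference of ratios therefore cannot be ascribed to the loss of 5-HT2C alone. With turned ratios, 4284 rows differed between WT and KO (limma interaction contrast, Benjamini-Hochberg), 1856 with the higher value in WT and 2428 with the higher value in KO. The difference exceeded 0.5 in 853 rows and 1 in 64 rows on the log2 scale. Row 35229 was higher in WT by 2.33 (SE 0.14; limma adjusted p = 4.81e-05), with means of 0.61 ± 0.32 in WT and -1.72 ± 0.18 in KO (SD, n = 4 each). Row 20686 was higher in WT by 2.23 (SE 0.20; limma adjusted p = 0.000254), with means of 0.69 ± 0.45 in WT and -1.54 ± 0.26 in KO (SD, n = 4 each). In the other direction, row 23099 differed by -1.14 (SE 0.13; limma adjusted p = 0.000673), with means of -0.79 ± 0.14 in WT and 0.35 ± 0.34 in KO. Row 7803 differed by -1.07 (SE 0.15; limma adjusted p = 0.00275) and had 3 WT values, with means of -0.74 ± 0.40 in WT and 0.32 ± 0.08 in KO. Without WT replicates 1, 2 or 3 the count was 2791, 2818 or 2773.

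As deposited, 16 rows differed between the genotypes by the same limma contrast, 15 with the higher value in WT and 1 with the higher value in KO. Leaving out any one of the 8 arrays gave 5 to 11 rows, and a dye term for each genotype, chosen after seeing the data, gave 106, of which 78 had the higher value in WT and 28 in KO. Row 18866 differed by 1.60 (SE 0.09; limma adjusted p = 0.000728), with a KO mean of 0.16 ± 0.23 (SD, n = 4). Row 42029 differed by 1.504 (SE 0.13; limma adjusted p = 0.0103), with a KO mean of 0.30 ± 0.25 (SD, n = 4). The row with the higher value in KO was row 27203, at -0.90 (SE 0.10; limma adjusted p = 0.0286), with a KO mean of 0.02 ± 0.14 (SD, n = 4). Over the 91 rows called in WT as deposited, the median ratio in the sign of the WT call was 0.50 in WT and 0.05 in KO (interquartile range 0.01 to 0.11), and 80.2% had the same sign in KO.

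The mean of both genotypes used all 8 arrays. With turned ratios 4238 rows differed from 0 (limma, Benjamini-Hochberg), 2037 positive and 2201 negative, but 23 exceeded 0.5 and 0 exceeded 1 on the log2 scale. Row 30846 had a mean ratio of 0.49 (SE 0.04; limma adjusted p = 0.000243) and the same sign on 8 of 8 arrays, with 0.26 ± 0.09 in WT and 0.71 ± 0.14 in KO (SD, n = 4 each). Row 39375 had a mean ratio of 0.48 (SE 0.05; limma adjusted p = 0.000882), also with one sign on 8 of 8 arrays. Row 42067 had a mean ratio of -0.69 (SE 0.10; limma adjusted p = 0.00253), with -0.31 ± 0.25 in WT and -1.06 ± 0.45 in KO (SD, n = 4 each). Row 27184, at -0.64 (SE 0.09; limma adjusted p = 0.00248), had its negative sign in KO, whereas its WT mean was 0.42 ± 0.41 (SD, n = 3). Without KO replicate 3 the count was 2643, and without WT replicates 1, 2 or 3 it was 2499, 2772 or 2733.

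As deposited, 38 rows passed for the mean of both genotypes (limma, Benjamini-Hochberg), 29 positive and 9 negative. Leaving out an array gave 18 to 26 rows, and a dye term for each genotype gave 236, with 121 positive and 115 negative. The highest was row 42029 at 1.05 (SE 0.07; limma adjusted p = 0.00127) and the next row 18866 at 0.96 (SE 0.04; limma adjusted p = 0.000197), and the larger part of both came from WT. The lowest were row 27203 at -0.42 (SE 0.05; limma adjusted p = 0.0231) and row 19328 at -0.37 (SE 0.04; limma adjusted p = 0.0363).

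The ratios of the genotypes were also set against each other across rows. The turned WT and KO ratios had a Pearson r of -0.072 and a Spearman rho of 0.0093 over 40891 rows, and the ratios as deposited had -0.015 and -0.028. Across rows these describe the arrays and carry no p-value. With turned ratios, 895 rows were called in both genotypes, where 424.9 would be shared by independent lists. Of these, 401 had the same sign (213.1 for independent lists) and 494 opposite signs (211.7), and their ratios had a Pearson r of -0.22 across rows. Of the rows called in WT, 47.3% had the same sign in KO, and of those called in KO, 48.3% had the same sign in WT. As deposited, no such count can be made from KO, where 0 rows were called, and 80.2% of the 91 rows called in WT had the same sign in KO at a smaller size. WT and KO share no array, but both lists come from one fit with one estimate of the spread per row, so rows of low spread can pass in both and the excess over independent lists does not measure a shared response.

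**Figure D3:**
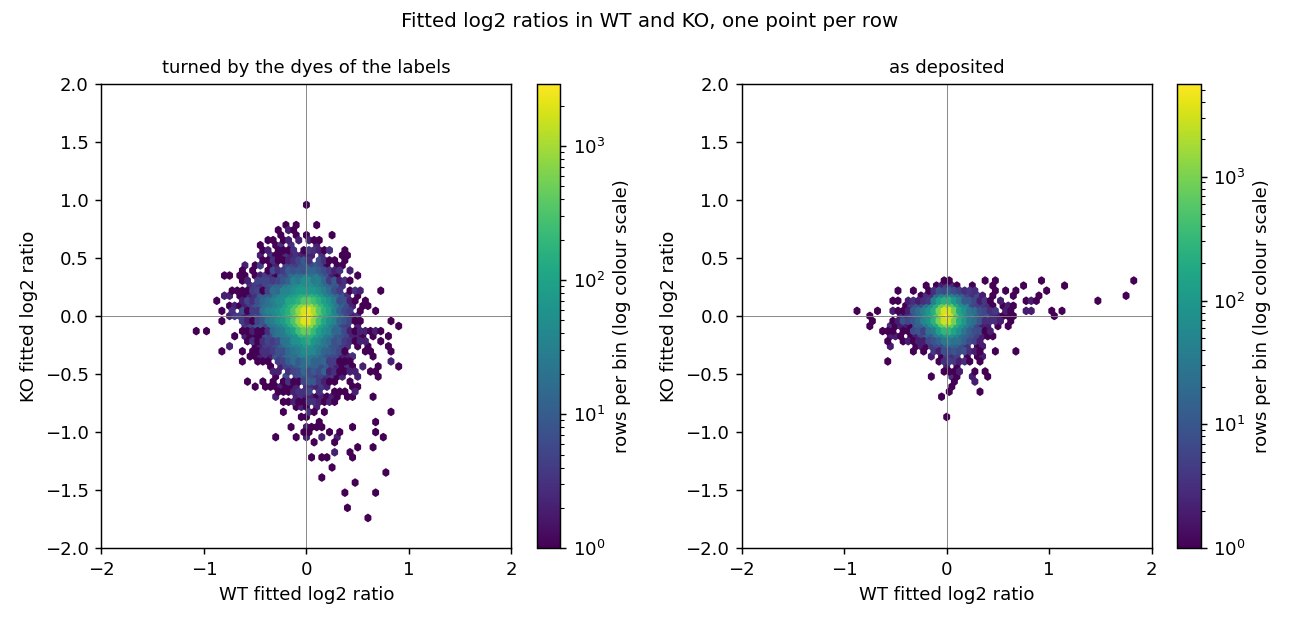
Fitted log2 ratio of each row in WT (horizontal) and KO (vertical), turned by the dyes (left) and as deposited (right), with colour for the number of rows per bin on a log scale. Turned, the most negative KO ratios reach -1.72 at WT values above 0. As deposited, the WT ratios lie between -0.87 and 1.80 and the KO ratios between -0.85 and 0.33.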

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

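All tests of explanations in this part, and those against other groupings of the arrays, were written down after the results were seen.

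The ratios of stimulated and unstimulated cells differed between WT and KO in 4284 rows with turned ratios and in 16 rows as deposited (limma interaction contrast, Benjamini-Hochberg). With turned ratios the WT minus KO differences on the log2 scale were 2.33 for row 35229, 2.23 for row 20686, -1.14 for row 23099 and -1.07 for row 7803. As deposited they were 1.60 for row 18866, 1.504 for row 42029 and -0.90 for row 27203. Of the 34 splits of the 8 arrays into 4 and 4 that were fitted, 1 gave as many rows, the real one. The real one gave 4284 and the highest other 16. The split with 16 holds the WT minus KO difference as deposited, so it is the second reading and not a chance pattern. Among the remaining splits the highest count was 4. Every other split mixes WT and KO arrays, so ratios that repeat within a genotype enter its residual and few rows can pass. Some also lack the dye balance of the real split. The splits show that the arrays group by genotype, and do not exclude chance for the turned count. One further split, by dye, could not be fitted. For the mean of both genotypes, 2 of 100 relabelings gave as many rows. They were the one turned by the dyes, with 4238, and the one that also changes the sign of a whole genotype, with 4284. The second is the WT minus KO difference and keeps what repeats within each genotype. The share is under 0.05, but the relabelings combine those of WT and of KO, too few in each alone. Chance is therefore not called excluded there either. Within WT the 4 arrays allow 8 relabelings, too few for a share under 0.05. The one turned by the dyes gave 4006 rows, and 1 of the 8 was as large. The highest other, with 22, holds the WT arrays as deposited, so it is the second reading and not a chance pattern. The rest gave 0 or 1. Within KO the same holds, with 4337 rows and 1 of 8 as large. The highest other, with 19, again holds the KO arrays as deposited, and the rest gave 0. With both genotypes as deposited in one fit, the counts were 91 in WT and 0 in KO.

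In 2 of 44 groups of 4 arrays tested, a single array lay far from the others, and chance gives about 2.2. KO replicate 1 had 10843 rows without a value, against 473 to 1608 on the other KO arrays. WT replicate 4 had a turned log2 ratio of -0.065 in row 37531, above the other 3 WT arrays.

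The ratios repeated between arrays of one genotype and changed sign with the dye. One candidate explanation is a dye difference of each probe, left in values that had already been turned before deposit. Were it alike in both genotypes, the turned WT and KO ratios would correlate. Their r of -0.072 (SD 0.046 over pairs of arrays) argues against it as the whole of the pattern. The same r argues equally against a serotonin response alike in both genotypes, in Cy5 over Cy3 values, as the whole of it. Rows were also put in 8 groups by how often they share values. In groups 4 to 8, with more shared values, WT and KO arrays of the same dye had a mean Spearman rho of 0.023 to 0.061. Those of opposite dyes had -0.080 to -0.027. These are the signs such a dye difference would give, so a small one is not excluded there. A response alike in both genotypes, in Cy5 over Cy3 values, would give the same signs. Groups 1 to 3 had the opposite signs (-0.087 to -0.010 and 0.0022 to 0.083). That the values were already turned is in line with the KO arrays, where a trend of the ratios along the row order, in the rows that most often share values, took opposite signs in arrays of opposite dyes (mean r of block means -0.46) and the same sign in arrays of one dye (0.44). WT leaned the same way more weakly and not in every pair. Its mean r was -0.12 for opposite dyes (from -0.23 to 0.017) and 0.21 for the same dye (from 0.10 to 0.33). WT replicates 1 and 4 had no trend beyond that of permuted rows, and WT replicates 2 and 3, of opposite dyes, gave the 0.017. Replicates 1 and 2 may also have been hybridised apart from replicates 3 and 4, and by chance 1 in 8 sign patterns over 4 arrays would follow the dyes. The stored precision followed the dye and not the replicate number in both genotypes (15 significant digits with stimulated RNA in Cy5, 6 in Cy3), so the arrays were written out differently by dye, which does not show the direction. A serotonin response in Cy5 over Cy3 values stays open as the biological explanation, if it is not wholly alike in WT and KO. The dye term common to both genotypes was called in 2 rows of the turned fit. The same quantity was called in 38 rows of the fit as deposited and in 236 with a dye term per genotype. None of these counts decides it, so response and a dye difference peculiar to each genotype's hybridisations cannot be told apart.

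The 91 WT rows with one sign in both dye assignments as deposited are the second pattern. A dye difference of each probe, alike in both genotypes and in Cy5 over Cy3 values, would give these rows about the same size in KO. Their median there was 0.047 against 0.50 in WT, which argues against it as the whole of the pattern, although 80.2% had the same sign in KO. The 91 rows were chosen by their WT values, which may raise their WT median but not that in KO. A serotonin response of WT cells in values already turned may account for them, as may a dye difference of the WT hybridisations alone. The 16 rows that differed from KO as deposited go with both, and these cannot be told apart without the direction of the deposited ratios.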

How the results depend on the processing

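The direction of the ratios decided the results, and every other setting moved the counts with turned ratios by less than 1.5 times, apart from leaving out arrays. As deposited, the rows called were 91 in WT, 0 in KO, 16 for the difference and 38 for the mean. With a dye term per genotype, chosen after seeing the data, they were 528, 0, 106 and 236. In KO, 1552 and 3083 rows had an unadjusted p under 0.05 (limma), below and above the share of 0.05 that chance gives. The Pearson r of WT and KO was -0.015 as deposited. Changes of sign on named rows came with the values as deposited: 0.066 for row 28310 and 0.077 for row 25774 in WT, -0.026 for row 37531 in KO, 0.012 for row 23099 and 0.20 for row 7803 in the difference, and 0.023 for row 42067 in the mean. The sign change of row 7803 was lost with the dye term per genotype. Turning the arrays is what sets these values apart. Which reading is right was not settled. Over all settings, leaving out arrays included, values of named rows kept direction and threshold in 275 cases, lost the threshold in 22 and changed sign in 11. Of the 22, 1 was with turned ratios: row 38804 had a limma adjusted p of 0.0514 with robust eBayes, and of 4.2e-05 to 0.0439 in the other settings with turned ratios.

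Leaving out each array gave 1826 to 3950 rows in WT, 2166 to 4021 in KO, 2773 to 3880 for the difference, 2499 to 3411 for the mean, and an r of -0.119 (without WT replicate 4) to -0.048, with fewer rows tested. Counts as deposited were 28 to 80 in WT, 0 in KO, 5 to 11 for the difference and 18 to 26 for the mean. Same-numbered WT and KO arrays had correlations of their deviations from the genotype means of -0.011, -0.046, -0.064 and -0.024, none over 0.1, so the numbers were not taken to pair the arrays. With the dye term in the fit, the consensus correlation of same-numbered arrays (duplicateCorrelation) was positive, at 0.111. Same-numbered WT and KO arrays always held the stimulated RNA in opposite dyes. A part of the ratios that follows the dye can therefore enter both measures, and neither decides whether the arrays are paired. With a replicate block, 4215 rows were called for the difference, and with a random replicate block 4106 in WT, 4437 in KO and 3583 for the mean. Gene lists, their alternatives and the restriction to rows with a gene symbol were not run, since row numbers did not match the probe table. Signal over background is unknown.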

Other observations

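All tests in this part were chosen after the results were seen.

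The third pattern was a mismatch between the row numbers and the genes that the probe table gives them. That the numbers match the table is argued against by rows of one gene symbol, whose ranks of shared values had a Spearman rho of -0.0078 (1000 permutations of the symbols gave -0.036 to 0.037). Rows listed as olfactory and vomeronasal receptors, expected to be silent in macrophages, had a value of their own in 23.5% of cases (mean over arrays), against 27.5% for ribosomal proteins and 22.4% for all rows with a symbol. Both classes lay inside the range of 95% of 10000 random lists of their size (20.3% to 24.5% and 15.8% to 29.0%), so a difference between them was not shown, and a small one is not excluded. Rows out of step between arrays are argued against as well, since the ranks of shared values correlated between every WT and KO array, with a lowest rho of 0.70. A candidate explanation is that rows were numbered in another array layout: the values of the 4 KO arrays repeated along the row order with a period of 215 rows, and the unnamed rows of the table with a period of 85. The WT arrays gave periods between 201 and 403 that differed from array to array, and no biological explanation was tested.

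The KO arrays had stronger trends along the row order than the WT arrays. In the rows that most often share values, the variance of block means was 6.09, 6.95, 10.3 and 13.2 times that of permuted rows for KO replicates 1 to 4, and 1.05, 1.64, 1.67 and 1.12 times for WT replicates 1 to 4. The highest of 100 permutations gave 1.37, 1.51, 1.42 and 1.38 for these WT arrays, so WT replicates 1 and 4 had no trend beyond chance by this measure.

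The number of distinct values per array was lower in KO (7084 to 10455) than in WT (13527 to 13957), with no overlap between the 4 and 4 arrays. Like the trends along the row order, this separates the arrays by genotype. Whether such differences between the arrays contribute to the rows that differ between WT and KO was not tested.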
